A study of Mus musculus with 2 samples.

How the data were processed

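The series holds 2 single-cell RNA libraries from mouse neural stem cell cultures. The control library came from wild-type cells, and the knockout library came from cells homozygous for a floxed Ppm1k allele. Cultures were prepared 3 times per genotype and pooled into a line, and both lines received an adenovirus carrying Cre recombinase and a green fluorescent reporter. Cells were collected 68 hours later. The growth medium held EGF, FGF and 10% serum. Capture used 10x Genomics droplets with a poly-dT primer, a 16 bp cell barcode and a 12 bp molecular identifier, per the labels' protocols. There was 1 library per genotype, so there is no replicate check of any difference, and genotype cannot be separated from culture line, capture or virus dose. By their sex-linked transcripts the lines also differed in sex, so genotype cannot be separated from sex either.

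Per the submitters' processing notes, the reads went through Cell Ranger and Seurat with the genome build mm10. Versions, cell filters, doublet treatment and clustering settings were not given in the sources used here. The headers of the cell type columns begin with RNA, and those of the cluster columns name no assay. The values used here are signal values that the authors deposited as means over cells, in 2 tables. In the deposited cell type table each of 10 columns is the mean over the cells of 1 of 5 cell types in 1 library. Each of its columns sums to 10000, so its values are mean counts per 10000 counts of a cell. In the deposited cluster table each of 34 columns is the mean over the cells of 1 of 17 numbered clusters in 1 library. Its values are signal in counts per cell. Column totals ran from 17265 to 20875 in the control library and from 14573 to 17770 in the knockout library. The counts may have been adjusted to a common depth, which no source states. The cell type names udNSCs, aNSCs, TA, iNeuron and Others are the authors' own and are used as deposited, without spelling them out.

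Every value of the cluster table was a whole multiple of 1 over a whole number, which is the number of cells in the cluster. The largest distance from a whole multiple was 0.000346, with a tolerance of 0.001, and 7 of 7 simulated cell numbers were recovered. The recovered cell numbers put all 17 cluster numbers in falling order of size. Multiplying back gave summed counts per cluster and library. A cluster was placed in the cell type whose column held no 0 for any gene detected in the cluster. Each of the 17 clusters had 0 contradicting genes in its own type. Clusters 0, 1, 2, 3, 4, 7 and 16 made up udNSCs, clusters 5 and 8 aNSCs, cluster 9 TA, cluster 11 iNeuron, and clusters 6, 10, 12, 13, 14 and 15 Others. By depth, udNSCs held 7859 control and 6469 knockout cells, aNSCs 256 and 2126, TA 69 and 933, iNeuron 140 and 354, and Others 1743 and 1485. These cell numbers are given as depth only, because there was 1 library per genotype. In addition, in 14 of the 17 clusters at least 1 of the 10 leading genes was 2-fold apart between the libraries.

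The cell type table had 19143 rows, and 19108 rows made up the table of clusters. In 23 rows a spreadsheet had turned the gene symbol into a date. These rows name no gene, held 0.0592% to 0.148% of a column, and were left out. The remaining tables shared 19085 symbols, and 35 stood in the cell type table alone. Of the 19120 symbols used, 18874 matched the GENCODE M21 annotation, which gave the coordinates on the mm10 assembly. No column with values was left unused.

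No test between genotypes was made, because cells, clusters and genes are not replicates. For each cell type the log2 ratio of knockout to control was taken after adding a pseudocount of 0.1 per 10000, which understates the ratio of weakly expressed genes. Genes with a mean of 0.5 per 10000 or more over the pair were compared, and a gene is described as 2-fold apart from a log2 ratio of 1 or -1 on. Summed counts carry an exact Poisson interval and shares of cells an exact Clopper-Pearson interval, both at 95%. These intervals cover counting error only, treat the summed values as plain counts, and say nothing about differences between cultures. At the level of the floor a gene rested on 7889 control and 5450 knockout counts in udNSCs, on 72 and 829 in TA, and on 136 and 286 in iNeuron. The upper limit of the counting interval at the floor lay 25.9% above the value for TA and 18.3% above it for iNeuron in the control library.

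A set of 39 gene lists, covering metabolism, stress, the cell cycle and markers of neural and other brain cell types, was compared by the median log2 ratio of the members at the floor, for lists with at least 3 of them. Each median is given as a percentile among 10000 random lists of the same size, drawn with replacement from 20 bins of mean expression. The percentile describes these libraries; members of a list vary together, so a list outside the central 95% is not a test result. Lists that reached 3 members in no cell type, such as the interferon response, gave no value.

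The pseudocount, the floor, the fold threshold, the percentile method, the lists and the rule for naming genes were set before the data were examined. Leaving out the date rows, recovering cell numbers, placing clusters in cell types and the counting intervals were not part of that plan. The rule named Ppm1k, the 10 highest and the 10 lowest ratios in each cell type, the genes 2-fold apart in the same direction in all cell types, and the 2 highest and 2 lowest members of each list outside the central 95% and of branched-chain amino acid breakdown. For cell type profiles it named the 5 genes with the largest ratio to the mean of the other columns, ranked with the pseudocount added. Only part of these genes is printed: list members are given mainly for udNSCs, and the others are summarised. The comparison of whole libraries from summed counts, and the alternatives without sex chromosome genes or without some clusters were chosen after seeing the data.

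On simulated tables drawn with Poisson noise at the real means and depths, 200 genes were altered in each cell type, 50 at each of 4 sizes. At 1.5-fold, 0 of 50 were called 2-fold apart in every type. At 2.5-fold the calls were 46 of 50 in udNSCs, 50 in aNSCs, 47 in TA, 46 in iNeuron and 48 in Others, and at 4-fold and 8-fold 50 of 50 in each type. With no alteration, 0 genes were called in any type, among 3233 tested in udNSCs and 2200 in iNeuron. Of 200 random lists, 11 in udNSCs, 14 in aNSCs, 4 in TA, 13 in iNeuron and 10 in Others fell outside the central 95%. The simulation holds no difference between cultures. It drew summed counts, so it also held no spread between cells and no averaging of per-cell values. The calls made without alteration therefore cover counting noise alone.

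Alternatives were other pseudocounts, floors and fold thresholds, rescaled or centred columns, totals without mitochondrial genome and ribosomal protein genes, cluster columns in place of cell type columns, other bins, and the mean in place of the median. For cluster columns each cluster was rescaled to 10000 and the median was taken over the clusters of a type. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.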

Results

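Gene expression was profiled in single cells of mouse neural stem cell cultures, to compare wild-type cells with cells homozygous for a floxed Ppm1k allele, both given Cre. The control library held 10067 cells and the Ppm1k knockout library 11367 cells. The mean count per cell was 19951 in the control library and 16931 in the knockout library, a ratio of 1.18. These are means of the deposited values, which may have been adjusted to a common depth, so the raw depth is not known. Cell type values are mean counts per 10000 counts of a cell, with 1 library per genotype and therefore no replicate error. The study addresses branched-chain amino acid metabolism in the nervous system, and the comparisons below describe how these 2 libraries differed.

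Ppm1k encodes the mitochondrial phosphatase that activates the branched-chain ketoacid dehydrogenase complex. It lies on chromosome 6 from 57506502 to 57535468 in mm10. Its level was lower in the knockout library, at 745 summed counts against 1709 in the control library. This was 0.455 of the control level per total count, with a 95% counting interval of 0.417 to 0.496. It was lower in 17 of 17 clusters. In udNSCs, Ppm1k stood at 0.0837 per 10000 in the control library and 0.0384 in the knockout library. The levels were 0.112 and 0.0453 in aNSCs, 0.0693 and 0.0350 in TA, and 0.0753 and 0.0257 in Others. In iNeuron they were 0.0247 and 0.0101, from 7 counts in each library, and the counting intervals of the summed counts overlapped there and in TA. All these levels were below the expression floor. The deleted exons were not given in the sources used here, and 3' tags outside them would not report the deletion.

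The lines also differed in sex-linked transcripts. Xist, the RNA that coats the inactive X chromosome of female cells, had 134504 counts in the control library and 46 in the knockout library. The Y chromosome gene Ddx3y had 0 control counts and 14073 knockout counts, Eif2s3y 0 and 9537, Uty 0 and 3919, and Kdm5d 12 and 4117. Xist was lower, and Ddx3y and Eif2s3y were higher, in the knockout library in 17 of 17 clusters. The X-linked genes Ddx3x, Eif2s3x, Kdm5c and Kdm6a, which escape X inactivation, had library log2 ratios of -0.30, -0.43, -0.37 and -0.39. The labels do not give the sex of the animals. By these transcripts the control library was female and the knockout library male, so every difference below is also one between lines of different sex.

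In udNSCs, which held most cells of both libraries, Fabp7, Olig1, Slc1a3 and Ccnd1 were among the genes higher in the knockout library, and Cst3, Igfbp5 and Col1a2 among those lower. Fabp7, the fatty acid binding protein of radial glia, was 1.09 per 10000 in the control and 5.50 in the knockout library. Olig1, a transcription factor of the oligodendrocyte lineage, was 0.330 and 1.68, and the glial glutamate transporter gene Slc1a3 was 0.488 and 1.82. The cyclin gene Ccnd1 was 4.56 and 14.3. Cst3, which encodes the secreted protease inhibitor cystatin C, was 135 in the control and 33.5 in the knockout library. Igfbp5, which encodes a binding protein of insulin-like growth factors, was 10.6 and 2.71, and the type I collagen gene Col1a2 was 9.77 and 2.60.

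Among 3235 genes at the floor in udNSCs, 29 were at least 2-fold higher and 41 at least 2-fold lower in the knockout library. The split was 76 and 60 with a floor of 0.1 per 10000 and 85 and 61 without a floor. The 10 highest also held Cadps, Peg3, Nkx6-2, the Hedgehog receptor gene Ptch1, Sparcl1 and Nnat, with log2 ratios from 1.60 for Nnat to 2.15 for Cadps. The 10 lowest also held Xist, the protease gene Prss23, Ptgds, the osteopontin gene Spp1, the proteoglycan genes Prelp and Ogn, and Rida. Leaving out Xist, their log2 ratios ran from -2.26 for Prss23 to -1.59 for Rida. By summed counts, Fabp7 in udNSCs was 1.11 per 10000 (1.09 to 1.13) against 5.68 (5.63 to 5.72), and Cst3 was 135.9 (135.7 to 136.1) against 33.5 (33.4 to 33.6). Clusters 0 and 2 held 32.6% and 23.1% of the control cells of udNSCs, and clusters 1 and 3 held 30.5% and 19.5% of the knockout cells. Of the 10 leading genes, 3 in cluster 4 were fibroblast markers such as Col3a1, and 2 in cluster 7 were smooth muscle markers such as Acta2. The clusters of udNSCs thus differed in leading genes, and whether they held other cell types was not tested. Compared cluster by cluster, the numbers higher and lower were 39 and 40 in cluster 0, 38 and 48 in cluster 1, 30 and 38 in cluster 2, and 29 and 32 in cluster 3. They were 33 and 39 in cluster 4, 18 and 25 in cluster 7, and 49 and 52 in cluster 16. Fabp7 was at least 2-fold higher in 17 of 17 clusters, and Cst3 was lower in 17.

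In aNSCs and TA, the same direction held for Fabp7, Nkx6-2, Nnat and Ptch1 on the higher side and for Igfbp5, Col1a2, Cst3 and the proteoglycan gene Bgn on the lower side. Fabp7 was 5.21 in the control and 12.9 in the knockout library in aNSCs, and its log2 ratio in TA was 1.94. The homeobox gene Nkx6-2 was 0.581 and 1.93 in aNSCs and 0.262 and 1.68 in TA. Igfbp5 was 4.17 and 0.663 in aNSCs and 2.71 and 0.478 in TA. The DNA-bending protein gene Hmgb2 and Id3, which encodes an inhibitor of basic helix-loop-helix factors, had log2 ratios of 1.06 and 1.05 in aNSCs, but Hmgb2 was at 0.66 as the median over clusters. In TA the folate enzyme gene Aldh1l1 had a log2 ratio of 1.29 and the matrix gene Mgp one of 1.24. Of 3326 genes in aNSCs, 8 were at least 2-fold higher and 20 lower; of 3462 in TA, 12 were higher and 21 lower. Cluster 8 held most control cells of aNSCs and cluster 5 most knockout cells. Control TA rested on 69 cells.

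In iNeuron, Trf, Nefl and Gal were among the genes higher in the knockout library, and Spp1 and Mmp3 among those lower. The transferrin gene Trf was 0.141 in the control and 2.49 in the knockout library, the neurofilament gene Nefl 0.194 and 1.57, the neuropeptide gene Gal 0.896 and 5.37, and the secretory granule gene Vgf 0.873 and 3.75. Dlk1, the stress cytokine gene Gdf15 and the imprinted RNA Meg3 had log2 ratios of 2.05, 1.92 and 1.89. Spp1 was 138 in the control and 7.19 in the knockout library, but 73.1 (72.0 to 74.1) and 6.63 (6.42 to 6.85) by summed counts of the same cells. The matrix protease gene Mmp3 was 6.98 and 0.678, but 3.04 and 0.458 by summed counts, and Trf was 0.0992 and 1.49 by summed counts. Mgp, Anxa1, Nupr1, the protease inhibitor gene Timp1, Serpinf1, the actin-binding gene Tagln and Ly6a were lower, with log2 ratios from -2.46 for Mgp to -1.88 for Ly6a. From cluster 11, with the same cells, Mgp, Anxa1 and Nupr1 were less than 2-fold apart, at -0.68, -0.84 and -0.79. Of 2189 genes, 77 were at least 2-fold higher and 46 lower. The median over all genes was 0.16 on the log2 scale; with ratios centred on it the split was 32 and 71, and with totals free of mitochondrial genome and ribosomal protein genes it was 56 and 66. From the column pair of cluster 11, which holds the same cells, 22 and 23 genes were 2-fold apart.

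In Others, Trf was 0.0767 and 1.36, Vgf 0.227 and 1.96, the neurofilament gene Nefm 0.129 and 1.23, and the growth factor gene Areg 0.169 and 1.15, with a log2 ratio of 2.22, but 0.74 as the median over clusters. Fabp7 was 0.374 and 2.11. On the lower side stood Spp1 at 34.4 and 6.46, Cst3 at 76.4 and 14.8, the calcium-binding gene S100a4 at 6.71 and 1.41, and Bgn at 5.85 and 1.23. As medians over clusters the log2 ratios were nearer 0 for Trf (2.18 in place of 3.04), Vgf (1.34 in place of 2.66), Nefm (1.46 in place of 2.54), Spp1 (-1.47 in place of -2.39), S100a4 (-1.15 in place of -2.17) and Bgn (-1.63 in place of -2.16). Tagln had a log2 ratio of -1.64, but 0.01 as the median over clusters. Of 3032 genes, 47 were at least 2-fold higher and 29 lower. The median over all genes was 0.21; the split was 24 and 59 after centring, 43 and 52 without mitochondrial genome and ribosomal protein genes, and 15 and 29 as the median over clusters. Clusters 6, 12 and 13 held most control cells of Others and clusters 6 and 10 most knockout cells. Cluster 12, with 22.6% of the control and 6.26% of the knockout cells of Others, had 40.2% ribosomal protein counts and Malat1 at 11.8 per 10000 in the control library, against 434 in cluster 6. Cluster 13, led by AY036118 and Gm42418, held 21.3% and 7.34%.

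Across all 5 cell types, 6 of 1684 genes were at least 2-fold lower in the knockout library and 0 were higher; Fabp7 did not reach the floor in iNeuron. The 6 were Igfbp5, Cst3, Bgn, Col1a2, Xist and Crym, which encodes a thyroid hormone binding protein. In udNSCs, aNSCs and TA together, 4 of 2826 genes were higher, namely Nnat, Nkx6-2, Fabp7 and Ptch1, and 12 were lower. This grouping of types was not planned in advance. The 12 added Gsn, Apoe, Mfge8, Prss23, the Wnt antagonist gene Sfrp1 and Ogn to the 6. Over the 17 clusters, Fabp7 was the gene 2-fold higher in each and Xist the gene 2-fold lower in each, among 3238 genes. With a pseudocount of 1 per 10000 the genes 2-fold apart numbered 20 in udNSCs, 9 in aNSCs, 10 in TA, 28 in iNeuron (12 higher and 16 lower) and 19 in Others (5 and 14), and with a floor of 0.1 per 10000 they numbered 136, 53, 78, 238 and 175. With a floor of 2 they numbered 27, 13, 9, 37 and 23, with 9 higher and 14 lower in Others. Of the 3238 genes, 150 were higher by any amount in 17 of 17 clusters and 67 were lower.

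**Figure D1:**
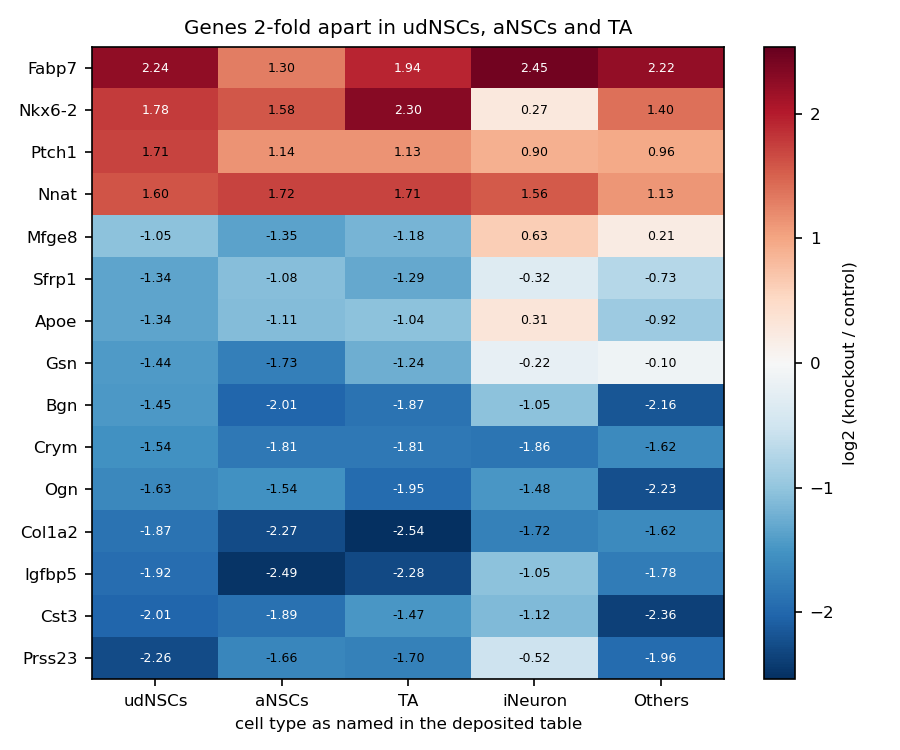
Log2 ratio of knockout to control (colour and printed value) for the 15 genes other than Xist that were at least 2-fold apart in udNSCs, aNSCs and TA, in each of the 5 cell types, with values below the floor also drawn. Fabp7 is above 1 in all 5 columns, while Mfge8 is below -1 in udNSCs, aNSCs and TA and above 0 in iNeuron and Others. The grouping of udNSCs, aNSCs and TA was not planned in advance.

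Among metabolic lists, branched-chain amino acid breakdown, the pathway in which Ppm1k acts, was slightly lower in the knockout library in udNSCs. The median log2 ratio of its 12 members at the floor was -0.18, at percentile 0.16 of random lists, with 10 members lower and 0 of them 2-fold apart. The lowest were the leucine pathway gene Auh at -0.45 and the acyl-CoA dehydrogenase gene Acadsb at -0.41, and the highest were Hsd17b10 at 0.12 and Echs1 at 0.08. The list median was -0.14 in TA (percentile 1.98), -0.06 in Others (percentile 0.82), -0.02 in aNSCs (percentile 34.2) and 0.04 in iNeuron (percentile 16.7). As the median over clusters it was -0.21 in Others and -0.08 in TA. Other mitochondrial lists had similar medians in udNSCs, at -0.19 for the citric acid cycle and -0.18 for the nuclear respiratory chain. Random lists were matched on expression only, so the percentile does not set this pathway apart from mitochondrial genes in general. Neutral amino acid carriers were higher, with a median of 0.80 over the 4 of 16 members at the floor in udNSCs and 0.91 in Others. Over clusters these medians were 0.69 and 0.65. In udNSCs the 4 were Slc38a2, Slc38a1, Slc6a6 and Slc3a2, so the leucine carrier gene Slc7a5 was not among them. The glutamine carrier genes Slc38a2 and Slc38a1 had log2 ratios of 0.92 and 0.85 in udNSCs, while Slc3a2, a partner of the leucine carrier, had -0.11. In aNSCs and TA the carrier medians were 0.39 and 0.28, but with a floor of 0.1 per 10000 they were -0.00466 and -0.15.

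Glycolysis genes were higher in udNSCs, aNSCs and TA, with medians of 0.42, 0.32 and 0.17. In udNSCs 11 of 16 members were higher, led by Pgk1 at 0.98 and Ldha at 0.79, whereas Ldhb was at -0.73 and Pfkm at -0.48. The glycolysis median was -0.35 in iNeuron and -0.22 in Others, but -0.03 in iNeuron from cluster 11 and 0.13 in Others as the median over clusters. Citric acid cycle genes were lower in udNSCs, where 24 of 24 members were below 0 with a median of -0.19. Their lowest members were Idh3a at -0.40 and Mdh1 at -0.37. Nuclear respiratory chain genes had a median of -0.18 in udNSCs, with 54 of 55 lower and Cycs at -0.37 and Ndufs1 at -0.35 the lowest. The 13 transcripts of the mitochondrial genome, also a sign of RNA quality, had medians of -0.20, -0.31 and -0.24 in udNSCs, aNSCs and TA. In Others their median was 0.16, but -0.04 after centring and -0.04 as the median over clusters. Lists of glutamate and GABA metabolism and of fatty acid metabolism had medians of -0.37 and -0.16 in udNSCs, with the glutamine synthetase gene Glul at -1.20 and the desaturase gene Scd1 at -1.18. Each list also held a gene more than 2-fold higher, Slc1a3 at 1.71 in the former and Fabp7 at 2.24 in the latter.

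Cytosolic ribosomal protein genes, another sign of RNA quality and of cell mix, went in opposite directions. In udNSCs 51 of 51 were higher with a median of 0.32, from Rpl10 at 0.11 to Rpsa at 0.64. The medians were 0.18 in aNSCs and 0.18 in TA. In iNeuron and Others 51 of 51 were lower, with medians of -0.51 and -0.54, but the median from cluster 11 was -0.20 in iNeuron and the median over clusters was 0.22 in Others.

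Marker lists of progenitors and of stromal cells were mixed. Of 12 oligodendrocyte precursor markers, 3 reached the floor in udNSCs. These were higher in the knockout library, with log2 ratios of 2.05 for Olig1, 1.49 for Ptprz1 and 0.83 for Vcan. Neural stem cell markers had a median of 0.22 in udNSCs and 0.64 in Others (0.33 over clusters), led in udNSCs by Fabp7 at 2.24 and Slc1a3 at 1.71, with Id4 at -0.66 and Lhx2 at -0.39. Their sum, however, was lower in the knockout library in udNSCs, at 145 and 129 per 10000, and in iNeuron and Others. It was higher in aNSCs, at 104 and 119, and in TA, at 89.2 and 103. Astrocyte markers went both ways in udNSCs, with a median of -0.36, Cst3 at -2.01 and Apoe at -1.34 against Sparcl1 at 1.66 and Aldh1l1 at 1.25. Extracellular matrix genes had medians of -0.22, -0.32 and -0.38 in udNSCs, aNSCs and TA, where 13 of 19, 13 of 15 and 15 of 17 members were lower. In udNSCs Col1a2 was at -1.87 and Thbs1 at -0.83, against Lama4 at 0.69. Fibroblast markers had medians of -0.28 in udNSCs, -0.09 in TA, inside the central 95% of random lists and with Mgp at 1.24, and -1.75 in iNeuron, where 4 members reached the floor and the median from cluster 11 was -0.49. Smooth muscle and pericyte markers had medians of -0.12 in udNSCs, inside the central 95%, -0.43 in aNSCs, -0.72 in TA and -1.16 in iNeuron, but 0.01 in aNSCs and 0.07 in iNeuron without a floor, and -0.58 in iNeuron from cluster 11. In Others their median was -1.24, but 0.07 as the median over clusters. Markers of microglia reached the floor in 0 of 12 cases in both libraries in every type.

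Amino acid sensing and mTORC1 genes and heat shock protein genes were inside the central 95% of random lists in all 5 cell types. Targets of ATF4, a factor of the amino acid response, were outside it in TA, with a median of -0.14, and inside it in the other 4. Notch genes had medians of 0.27 in TA and 0.89 in Others (0.35 over clusters), and targets of Wnt and BMP had medians of 0.64 in iNeuron (0.19 from cluster 11) and 0.51 in Others (0.11 over clusters). Immediate early genes had medians of 0.26 in udNSCs and 0.85 in Others, but 0.08 and 0.34 over clusters, with Ier3 at 0.86 and Jun at 0.65 in udNSCs. Arrest and p53 target genes had a median of 0.63 in Others, where 15 of 17 members were higher, with Pmaip1 at 1.28 and Cdkn1a at 1.08, but the median over clusters was 0.12. The inflammatory list had a median of -0.91 over 4 members in udNSCs, with the adhesion gene Vcam1 at -1.26 and the chemokine gene Ccl2 at -1.26. Antioxidant genes had a median of -0.13 in udNSCs (-0.07 over clusters), with Hmox1 at -0.78. Hypoxia response genes had a median of -0.35 in Others, but 0.11 as the median over clusters. The list of immature neurons had a median of -0.33 over 5 members in udNSCs, with Tubb3 at -0.88, but -0.13 over clusters and 0.09 with totals free of mitochondrial genome and ribosomal protein genes. Within aNSCs, 29 of 30 mitotic genes were higher, with a median of 0.41, but 0.14 as the median over clusters. The mitotic cluster 5 held 42.6% of control and 57.9% of knockout cells of aNSCs, and the median of its 10 leading genes within it was -0.04. Within TA 30 of 33 mitotic genes were higher, with a median of 0.11. Mitotic genes in Others had a median of 0.99 (0.46 over clusters), and S phase genes in aNSCs had one of 0.47 (0.30 over clusters). Few members of these lists reached the floor there, such as 3 of 30 S phase genes in control aNSCs. Of the lists that could be compared, 18 of 29 in udNSCs, 15 of 31 in aNSCs, 16 of 30 in TA, 6 of 28 in iNeuron and 22 of 29 in Others lay outside the central 95% of random lists.

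**Figure D2:**
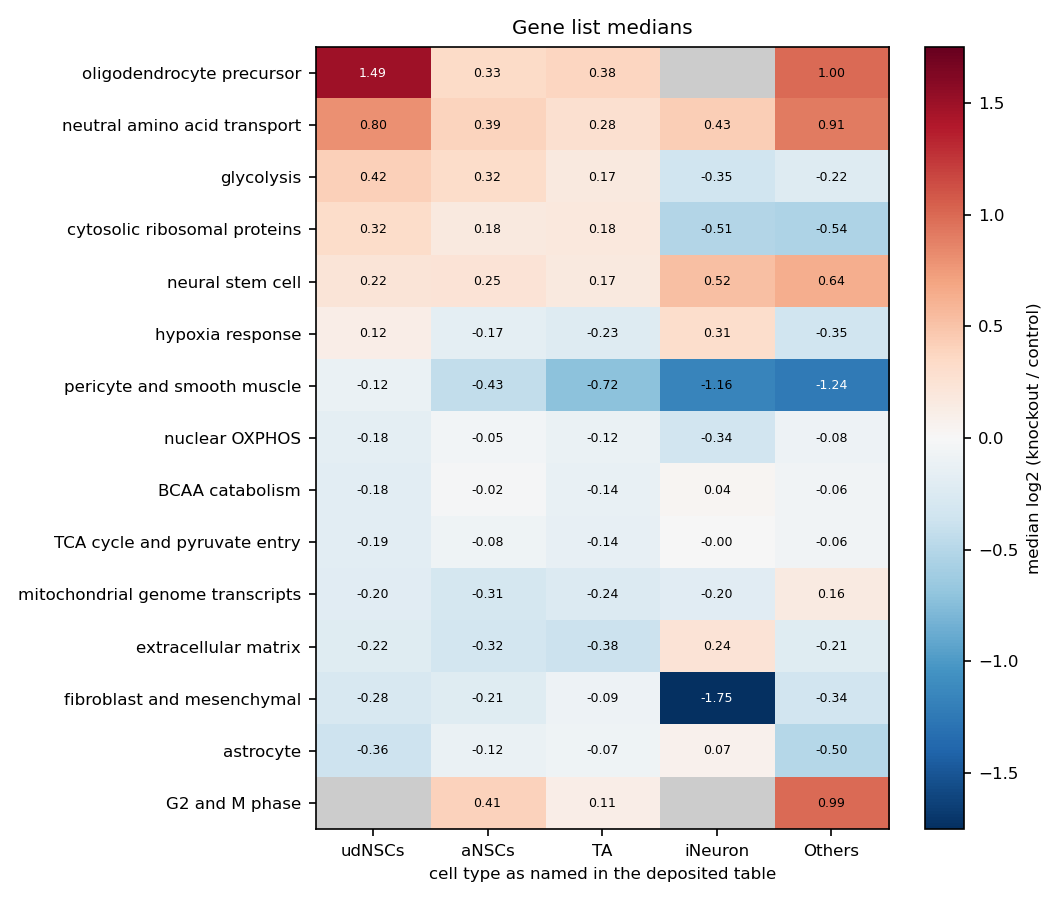
Median log2 ratio of knockout to control (colour and printed value) for the 15 gene lists outside the central 95% of random lists in at least 3 cell types, by cell type; grey marks lists with fewer than 3 members at the floor. Neutral amino acid transport is above 0 in all 5 columns, and ribosomal proteins run from 0.32 in udNSCs to -0.54 in Others, where the median over clusters was 0.22.

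The genotype ratios of udNSCs, aNSCs and TA resembled each other more than those of iNeuron. Across genes, which are not independent replicates, Pearson's r was 0.82 between aNSCs and TA (Spearman's rho 0.68, 3094 genes) and 0.79 between udNSCs and aNSCs (rho 0.69, 2989 genes). It was 0.75 between udNSCs and TA and 0.58 between iNeuron and Others. Between iNeuron and udNSCs, aNSCs or TA it was 0.22, 0.21 and 0.17, with rho at 0.0657, 0.00842 and -0.0381 and 54.7%, 49.4% and 47.9% of genes of the same sign. The mean over the 10 pairs of types was 0.494, and 0.443 without genes of the X and Y chromosomes. No correlation is given for cluster columns, from which 45 genes in place of 123 were 2-fold apart in iNeuron. All 5 types came from the same pair of libraries.

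The cell type columns were told apart by cell cycle genes in TA and aNSCs. In TA of both libraries the linker histone gene Hist1h1b, the replication gene Pclaf, Hist1h2ap and Atad2 were among the 5 leading genes. Hist1h1b was 10.2 per 10000 in control TA, 112-fold the mean of the other types. In aNSCs the leading genes of both libraries included Cenpa and Ccnb2, genes of mitosis. In control aNSCs the leading genes also held Kcnc1 at 6.32-fold, Fabp7 at 4.86-fold and Ptprz1 at 4.02-fold. In iNeuron both libraries shared Efna3, Pou3f1 and the cell cycle inhibitor gene Cdkn1c. The control column also led with Mmp3 and the knockout column with Gal and Dlk1. Of 19 immature neuron markers in the table, 2 reached the floor in control iNeuron and 4 in knockout iNeuron, and of 19 mature neuron markers 3 and 4. In udNSCs the numbers were 5 and 7 for immature and 1 and 2 for mature neuron markers. Summed immature neuron markers were lower in iNeuron than in udNSCs, at 6.27 against 12.0 per 10000 in the control and 10.2 against 11.4 in the knockout library. Summed mature neuron markers were higher, at 3.49 against 1.48 and 5.59 against 2.13. In udNSCs both libraries shared Ahr, Ogn and Igfbp5, and Others shared Hist1h2bc and Mpp1. Genes at least 2-fold above the mean of the other types numbered 352 in control and 281 in knockout TA, 241 and 497 in iNeuron, 77 and 52 in udNSCs, 63 and 56 in aNSCs, and 12 and 74 in Others. Summed over the 10 columns they made 1705 pairs of gene and column.

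Over whole libraries, compared by summed counts without using cell types, cell cycle genes were higher in the knockout library. This comparison was chosen after seeing the data. The 35 genes of G2 and M phase summed to 5.20 per 10000 (5.17 to 5.23) in the control and 24.4 (24.3 to 24.5) in the knockout library, a 4.69-fold difference, and 34 of them were at least 2-fold higher. The 30 genes of S phase summed to 3.07 (3.05 to 3.09) and 8.42 (8.37 to 8.46), with 26 at least 2-fold higher. The counts of 34 and 26 are of plain ratios, without the pseudocount or the floor. Only 10 of the 65 cell cycle genes reached the floor over whole libraries. The proliferation marker Mki67 had a log2 ratio of 2.57, and the topoisomerase gene Top2a was 0.278 and 2.19. Among 3229 genes at the floor, and with the pseudocount, 44 were at least 2-fold higher and 40 lower. The numbers were 23 and 38 without clusters 5, 8 and 9, and 153 and 62 with a floor of 0.1 per 10000. The 10 highest were Hist1h1b, Top2a, Pclaf, Mki67, Fabp7, Cenpf, Ube2c, Prc1, Olig1 and Hmgb2, and the 10 lowest were Xist, Igfbp5, Cst3, Prss23, Col1a2, Ogn, Rida, Spp1, Crym and Lrrn3. Without clusters 5 and 9, which mitotic and replication genes lead, the log2 ratio of summed cell cycle genes was 0.55 in place of 1.99. With each cluster given equal weight it was 0.29.

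Cluster 5, whose cells express mitotic genes, and cluster 9, whose cells express replication genes, held mostly knockout cells, with 933 of 1002 in cluster 9. Summed S phase genes were 40.7 per 10000 in control TA, which is cluster 9, and 42.8 in knockout TA, so the state was present in both libraries. With 1 library per genotype, how often it occurred cannot be told from a feature of the library. Shares of clusters among all cells of a library are not compared, because in 14 of 17 clusters at least 1 of the 10 leading genes was 2-fold apart within the cluster. In clusters 5, 9 and 14 there were 0, so there the reason is that each genotype had 1 library. In the cells outside these clusters, 6, 3 and 2 of the 10 were 2-fold apart. For clusters 5 and 9 this can follow from their cell numbers, because the cells outside each include the other. Summed G2 and M phase genes were 73.3 per 10000 in control TA and 84.4 in knockout TA.

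**Figure D3:**
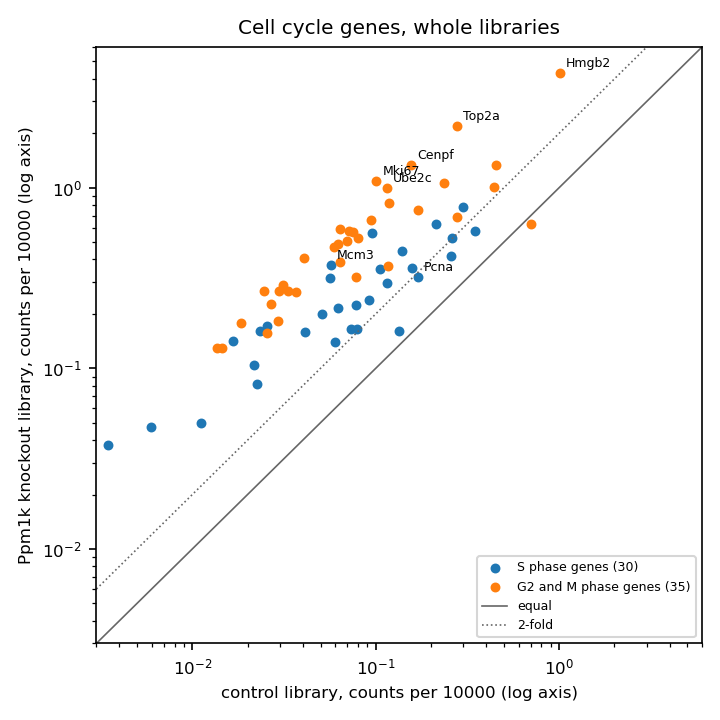
Summed counts per 10000 of each cell cycle gene in the control library (horizontal, log axis) and the knockout library (vertical, log axis), with 30 S phase and 35 G2 and M phase genes; the solid line marks equal levels and the dotted line a 2-fold difference. Of the G2 and M phase genes, 34 lie at or above the dotted line, as do 26 of the S phase genes.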

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

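The tests in this part were chosen after the results they test had been seen, except that comparing cluster columns was planned in advance. The following results differed in sign between cell types, and the differences themselves were not tested. Glycolysis genes had a median log2 ratio of 0.42 in udNSCs and -0.35 in iNeuron, the latter -0.03 from cluster 11. Transcripts of the mitochondrial genome had a median of 0.16 in Others (-0.04 over clusters) and -0.31 in aNSCs. Ribosomal protein genes had a median of 0.32 in udNSCs and -0.54 in Others (0.22 over clusters). Mgp was at 1.24 in TA and -2.46 in iNeuron, the latter -0.68 from cluster 11 with the same cells. Nupr1 was at 1.31 in udNSCs and -2.31 in iNeuron, the latter -0.79 from cluster 11. The nuclear RNA Neat1 was at 1.30 in Others and -1.33 in TA.

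Cell cycle transcripts were higher in the knockout library, and a lower depth per cell could shift weak genes. Their median log2 ratio was 1.14 over 65 genes with a floor of 0.02 per 10000. Matched random lists gave 0.03 to 0.14, so a shift shared by genes of the same level does not account for it. The raw depth of the libraries is not known, because the deposited counts may have been adjusted. For summed cell cycle genes the log2 ratio was 1.99, with 0.55 without clusters 5 and 9 and 0.29 with equal weight per cluster. Clusters 5 and 9 are led by mitotic and replication genes and held mostly knockout cells, so leaving them out lowers the ratio by construction. Equal weights set aside differences in cell number. The cause of the higher cell cycle transcripts could be loss of Ppm1k, but it could equally be the growth state of this culture line. With 1 line per genotype, and with Xist at a log2 ratio of -6.05 between them, no value here decides.

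Ribosomal protein transcripts were lower in Others and iNeuron. In Others the cluster mix may account for part of this, beside the averaging of cells: without cluster 12, where ribosomal proteins lead and most cells are control cells, the median log2 ratio from summed counts was 0.0835, against -0.33 with all clusters summed, and 4 of 6 clusters had medians above 0. In iNeuron the way per-cell values were averaged in the 2 tables could matter, since the median from cluster 11, with the same cells, was -0.20 in place of -0.51, which does not settle it. No biological explanation was tested for this pattern.

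The sex-linked transcripts could come from pools of mixed sex or from lines of different sex. An allowance of 3 counts in the control library would be 0.0204% of the knockout level of Ddx3y, and Xist in the knockout library was 0.0357% of its control level, so cells of the other sex could make up little of either pool. Kdm5d had 12 control and 4117 knockout counts, of which 7 and 277 were in Others, where Ddx3y had 0 and 1858; the source of these 12 was not tested. Genes on X or Y made up 2.86% of the genes 2-fold apart in udNSCs, namely Bgn and Xist, against 3.21% of the genes compared; Y genes such as Ddx3y lay below the floor in udNSCs and could not enter this share. Position on a sex chromosome therefore does not account for most of the list. Effects of sex on other chromosomes cannot be told apart from those of genotype in this design.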

How the results depend on the processing

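Of the 77 list medians outside the central 95%, the numbers outside on the same side were 77 with a pseudocount of 0.01 per 10000, 75 with 1, 77 after centring, 75 with 50 bins, 60 with the mean, 64 with a floor of 0.1, 54 without a floor and 59 with cluster columns. They were 32 of 48 with a floor of 2 per 10000 and 65 of 68 without mitochondrial genome and ribosomal protein genes. Of 98 named ratios at least 2-fold apart, 57 remained so with a pseudocount of 1 and 88 with cluster columns. Rescaling columns to equal totals hardly alters them, and 76 of the 77 stayed outside on the same side. With a pseudocount of 0.01 the log2 ratio of Ppm1k in udNSCs was -0.95, and 116 genes were 2-fold apart in Others. With a pseudocount of 1 it was -0.0616; genes 2-fold apart were 20 in udNSCs, 9 in aNSCs, 10 in TA, 28 in iNeuron, 19 in Others and 28 over whole libraries, and pairs of gene and column in the profiles were 440. A larger pseudocount shrinks ratios of weak genes by construction. With a floor of 0.1 per 10000 the 2-fold genes were 136, 53, 78, 238 and 175 in the same order and 215 over whole libraries, with 14 lists outside in iNeuron. Medians that turned were glutamate and GABA metabolism in Others (0.00825), the inflammatory list in Others (0.19), immature neurons in udNSCs (0.20) and neutral amino acid transport in TA (-0.15) and aNSCs (-0.00466). With a floor of 2 the 2-fold genes were 27, 13, 9, 37 and 23, and 29 over whole libraries, with 582 pairs in the profiles. The mean correlation between types was then 0.427, and lists outside were 8 in udNSCs, 9 in TA, 2 in iNeuron and 9 in Others. Without a floor the 2-fold genes were 146, 54, 89, 257 and 188, the mean correlation was 0.424 and 11 lists were outside in iNeuron. Medians that turned then were glutamate and GABA metabolism (0.0429) and the inflammatory list (0.0747) in Others, immature neurons in udNSCs (0.0439), neutral amino acid transport (-0.0238) and oligodendrocyte precursors (-0.0285) in aNSCs, and smooth muscle and pericyte markers in Others (0.0409), aNSCs (0.0068) and iNeuron (0.0739). These floors change which genes are compared. With cluster columns 45 genes were 2-fold apart in iNeuron and 44 in Others, with 10 lists outside in iNeuron. Turned in Others were ribosomal proteins (0.22), glycolysis (0.13), hypoxia response (0.11), mitochondrial genome transcripts (-0.0376), smooth muscle and pericyte markers (0.0655) and Tagln (0.01003). After centring, mitochondrial genome transcripts in Others were at -0.0431, and without mitochondrial genome and ribosomal protein genes the immature neuron list in udNSCs was at 0.0938. Without genes of X and Y the mean correlation was 0.443. At 1.5-fold the genes apart were 199, 99, 122, 524 and 432, and at 4-fold 6, 4, 4, 13 and 11. Compared with the highest other column, the profiles held 781 pairs. The log2 ratio of summed cell cycle genes was 0.55 without clusters 5 and 9, 0.53 without 5, 8 and 9, 1.95 without 12 and 13, and 0.29 with equal weights. Leaving out clusters 5 and 9, which mitotic and replication genes lead, lowers this ratio by construction. Except where construction is named, the cause was not tested. Tolerances for calling a value moved were set after the data were seen. Depth limits Ppm1k in iNeuron, with 7 counts per library, and weak genes in control TA. No paired analysis was possible because each genotype has 1 library.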

Other observations

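The tests in this part were chosen after the results were seen. Nnat, Peg3, Dlk1 and Meg3, named above, are imprinted genes, and a hypothesis was that imprinted genes as a class stood further apart than others. The 7 imprinted genes at the floor in udNSCs that the text had not named had a mean absolute log2 ratio of 0.239, at percentile 68.56 of matched random lists with an upper limit of 0.432, which does not decide it. With Nnat, Peg3 and Meg3, which the text had named, the mean over 10 genes was 0.528, which rests on the genes that prompted the question.

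A floxed allele can carry flanking sequence of another strain, so genes within 10 Mb of Ppm1k on chromosome 6 might have differed more often. Of 20 such genes at the floor in udNSCs, 0 were 1.5-fold apart (0 to 16.8%), against 6.16% of 3197 other genes, which does not decide it. By chromosome, the median log2 ratio in udNSCs ran from 0.00 to 0.07 over the 19 autosomes and was 0.07 for 104 genes on X.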
